A study of Mus musculus with 4 samples.

How the data were processed

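Liver sections of 4 wild-type mouse samples were profiled, 2 labelled GDF15 and 2 labelled caloric restriction. Per the labels' protocols, tissue was fixed in formalin, embedded in paraffin, sectioned, stained and imaged. Probe pairs against the whole transcriptome were hybridised, ligated and transferred to CytAssist slides with barcoded spots, and libraries were sequenced on an Illumina instrument. The authors ran the Space Ranger count pipeline, per the labels, on mm10, per the submitters' processing notes. The version of Space Ranger and the probe set are not given in the sources used here. The deposited counts are whole-number UMIs per gene and spot, not normalized, with 1 matrix per section and 19465 features. The spots in each matrix were those the authors' position tables mark as lying over tissue. Because probes were counted, a value depends on the binding of few probe pairs per gene, genes with close relatives can share probes, and no mitochondrial transcript was counted. The authors' deposited table of spatial enrichment gives a score per gene, Moran's I, with its p-value and adjusted p-value, per the file headers. Scores were used as deposited and the deposited p-values were not tested further.

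Groups came from the treatment label. The section was the replicate, never the spot, and raw counts were summed over all spots of a section. In R 4.3.3, edgeR 4.0.16 was run with TMM scaling, filterByExpr with its default minimum count of 10, and the quasi-likelihood test without robust fitting. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a common biological coefficient of variation of 11.9%. Gene symbols shared by more than 1 feature (11 symbols, 22 features) were kept apart by identifier. Levels are CPM, UMIs per 1000000 of the section after TMM scaling. Before averaging, sections of a group were compared: chi-square per degree of freedom was 21.4 between the GDF15 sections and 48.9 between those from caloric restriction, over genes with at least 20 UMIs in the pair, so neither pair looked like 1 library deposited again.

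Lists of pathway genes and cell type markers were fixed before the data were examined, and the 29 with at least 5 tested members entered camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The 2 lists of zone landmarks were not tested. Members with no row in the matrix, such as Saa1 and the landmark Glul, are not analysed here. A list is described where it passed camera or at least 3 members passed over all genes.

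For zonation, each spot was scored as the mean z-score of log2(CPM + 1) over central landmarks (such as Cyp2e1 and Oat) minus that over portal landmarks (such as Cyp2f2 and Hal). Within each section, spots were divided by rank into 3 parts of equal size: the portal zone (1621 to 1655 spots), a middle part that was left out, and the central zone (1621 to 1654 spots). The zones are ranges of a score, not cell types. Between 625 and 698 spots per section lay within 0.1 SD of a boundary. Counts were summed per section and zone, landmark genes were left out, and edgeR was fitted with section as a block, for zone and for the zone by treatment interaction. Ratios per section add 0.5 CPM. Shares of spots were taken after thinning each spot to 2000 UMIs, the largest preset depth that 90% of spots reached in every section, and were compared by an exact permutation test over sections.

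Genes are named by a rule fixed before the data were examined. For each comparison these are the 10 largest changes in each direction (5 within zones) among genes past the threshold. They had a mean of at least 10 CPM in the higher group and no overlap between groups. In the comparison of central with portal zone, genes instead had to differ the same way in all 4 sections. For the interaction, where fewer than 10 genes passed, they are the 10 smallest p-values among genes that met the other conditions, and genes with smaller p-values that did not meet them were passed over. Up to 4 members per list by smallest p, with a mean of at least 10 CPM, and a fixed set of genes of interest were added. Other members that passed are named where a count is listed in full, and said to be chosen afterwards where the rule does not name them. Some genes that the rule names are not reported here. The edgeR steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For whole sections 100% of both were recovered, and 11.5% of all calls were false. For the zones 100% of both were recovered, with 6.10% false calls. Both shares of false calls lay above what the adjusted p threshold allows, so the real calls may hold more false ones than it implies. The changed genes were all drawn from those with a mean of at least 10 CPM. Recovery was not split by expression level, and it cannot be taken to hold for genes with lower counts.

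Alternatives were DESeq2 1.42.0, RLE size factors, total UMIs alone, no filter or a filter of 10 CPM, limma-voom, equal weighting of spots, a minimum of 2000 UMIs per spot, thinning of sections to 35192332 UMIs, other zone widths and landmarks, and each section left out in turn. A pair of alternatives was chosen after seeing the data: leaving out genes of the non-hepatocyte marker lists, and leaving clock genes out of the other lists. Data were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Coordinates are from RefSeq's annotation of GRCm38.p6, the assembly that mm10 names. No slide, batch or date is given in the sources used here, so none could be tested.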

Results

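The data were 4 spatial transcriptome profiles of formalin-fixed, paraffin-embedded liver from wild-type mice. Sections of 2 samples labelled GDF15 (replicates 10 and 11) and 2 labelled caloric restriction (replicates 18 and 19) were profiled by probe hybridisation on arrays of barcoded spots, each spot covering a small area that can hold several cells. GDF15 is a circulating stress-induced cytokine that lowers food intake through a hindbrain receptor, and caloric restriction lowers intake directly. The title of the series names liver inflammation, weight loss and glucocorticoid signalling as its subject. The contrast available here is therefore between livers of the 2 groups, and every difference below is GDF15 relative to caloric restriction, with no untreated section in the comparison. Tissue covered 4863, 4879, 4924 and 4963 of 4992 spots in GDF15 replicates 10 and 11 and caloric restriction replicates 18 and 19. In the same order the sections held 35192332, 53460194, 102001858 and 45529358 UMIs (unique molecular identifiers, which count captured probe molecules), with medians of 6460, 10349, 19429 and 8355 UMIs per spot. The labels do not state that the sections came from separate animals, so edgeR p-values measure the spread between these sections, which may be partly technical. Camera with a preset correlation of 0.01 instead sets the genes of a list against all other genes and treats them as nearly independent. In every list that passed, the estimated correlation was higher, for example 0.55 for glucocorticoid receptor targets, 0.48 for lipogenesis and 0.96 for Kupffer markers.

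Over whole sections, 82 genes were higher and 122 lower in the GDF15 group among 18819 tested (edgeR quasi-likelihood test, adjusted p under 0.05). In each gene named here by size of change, both sections of one group lay above both of the other, as the naming rule required. The largest increases included Atp2b2, a plasma membrane calcium pump, at 19.5 ± 5.00 against 5.36 ± 1.71 CPM (UMIs per 1000000 after scaling; SD, n = 2 per group; log2 change 1.88 ± 0.25 SE, edgeR adjusted p = 0.0192). Bcl6, a zinc-finger transcriptional repressor, rose from 20.7 ± 1.01 under caloric restriction to 74.8 ± 11.2 CPM (SD, n = 2; log2 change 1.85 ± 0.13 SE, edgeR adjusted p = 0.00466). Further increases of at least 1.24 on the log2 scale were seen in Arntl, Lpin1, Zbtb16, Chrna4, Fasn, Ppp1r3b, Slc30a10 and Acly. Among these, Ppp1r3b, which targets a phosphatase to glycogen, was 2.38-fold higher and the manganese exporter Slc30a10 also 2.38-fold higher. The nicotinic receptor subunit Chrna4 was 2.80-fold higher. The largest decrease was in Clec2h, a C-type lectin, at 1.07 ± 0.686 against 12.3 ± 5.38 CPM (SD, n = 2; log2 change -3.46 ± 0.43 SE, edgeR adjusted p = 0.0153). Themis fell by 2.50 on the log2 scale (edgeR adjusted p = 0.00257), from 13.6 ± 0.768 to 2.40 ± 0.0575 CPM (SD, n = 2). Cidec, a lipid droplet protein, averaged 11.7 CPM after GDF15 and 51.5 under caloric restriction, a 4.45-fold decrease. The remaining named decreases were Usp2, Dbp, Cntnap1, Nrep, Per3, Pnldc1 and Osbpl3, with log2 changes from -2.34 to -1.38. The count depended on single sections: it was 32 without GDF15 replicate 10 (18 higher and 14 lower), 27 without GDF15 replicate 11 (15 higher and 12 lower), 596 without caloric restriction replicate 18 and 400 without caloric restriction replicate 19. DESeq2 called 754 genes, and 28.8% of its calls were higher against 40.2% in edgeR, while scaling by total UMIs alone gave 49.7% and equal weighting of spots with limma 52.3%.

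Of 20 tested glucocorticoid receptor targets, 5 rose and none fell over all genes, while 10 were higher and none lower when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 4.34e-12), with adjusted p = 0.793 with an estimated correlation. None of 29 lists passed camera with an estimated correlation, and lists with unadjusted camera p from 0.105 to 0.41 shared this adjusted value. That alternative therefore cannot tell the lists apart. Tsc22d3, an anti-inflammatory leucine zipper protein induced by glucocorticoids, was at 228 ± 7.21 against 115 ± 1.94 CPM (SD, n = 2; log2 change 0.99, edgeR adjusted p = 0.00782). Lpin1, a phosphatidate phosphatase, was 3.26-fold higher at 279 against 85.6 CPM (edgeR adjusted p = 0.00613). Zbtb16, a zinc-finger regulator, and Tat, the first enzyme of tyrosine breakdown, rose by 1.53 and 0.88 on the log2 scale (edgeR adjusted p = 0.0101 and 0.0234). Fkbp5, a chaperone that restrains the receptor, was at 66.5 ± 4.94 against 34.2 ± 8.47 CPM (SD, n = 2; edgeR adjusted p = 0.0451). The receptor itself, Nr3c1, was at 60.2 ± 1.64 and 59.2 ± 3.94 CPM (SD, n = 2; edgeR adjusted p = 0.922), and Hsd11b1, which regenerates active glucocorticoid, at 1031 and 899 (edgeR adjusted p = 0.386). Per1, another target, had a log2 change of -0.16 (edgeR adjusted p = 0.637). Members Mt1 and Mt2 were 5.96-fold and 7.99-fold higher in GDF15 replicate 11 than in GDF15 replicate 10. The GDF15 sections thereby lay on opposite sides of both sections from caloric restriction. Mt1 was at 163 and 972 CPM in GDF15 replicates 10 and 11, against 802 and 564 in caloric restriction replicates 18 and 19. In the same order Mt2 was at 78.0 and 627 against 285 and 207. The list stayed upwards in camera with each section left out in turn, most weakly without GDF15 replicate 11. Erythroid transcripts were lower in the same GDF15 sections, Hba-a2 at 28.2 against 58.1 CPM.

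In the lipogenesis list 6 of 18 members rose and none fell over all genes, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.23e-10, and adjusted p = 0.793 with an estimated correlation). Fasn, fatty acid synthase, was at 868 ± 104 against 332 ± 27.3 CPM, and Acly, which makes cytosolic acetyl-CoA, at 570 ± 40.9 against 241 ± 1.88 (SD, n = 2; edgeR adjusted p = 0.00755 and 0.00667). The carbohydrate-response factor Mlxipl rose by 0.74 on the log2 scale (edgeR adjusted p = 0.0264). Cholesterol synthesis genes passed as a list (camera adjusted p = 0.00228, and adjusted p = 0.793 with an estimated correlation), although none of 19 members passed over all genes and 6 were higher adjusted over the list alone. Insig1, a regulator of sterol synthesis, was at 624 against 393 CPM (edgeR adjusted p = 0.0536). For gluconeogenesis and amino acid breakdown, 1 of 17 members rose over all genes, the coactivator Ppargc1a at 26.8 against 16.0 CPM (edgeR adjusted p = 0.0182). Adjusted over the list alone, 5 were higher and 1 lower (camera adjusted p = 0.0119, and adjusted p = 0.793 with an estimated correlation), among them Sds and G6pc at 364 and 386 against 225 and 303 CPM. The gluconeogenesis call was lost without GDF15 replicate 11 (camera adjusted p = 0.212) and without caloric restriction replicate 19 (0.299), and the cholesterol call without caloric restriction replicate 19 (0.440).

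Of 17 circadian clock genes, 2 rose and 5 fell over all genes, and 5 rose and 11 fell adjusted over the list alone. The list passed camera downwards (adjusted p = 6.16e-05, and adjusted p = 0.793 with an estimated correlation). It mixes genes that peak at opposite times of day, so this direction follows the make-up of the list and does not show a lower clock. Arntl, the core activator of the clock, was at 28.5 ± 3.71 against 8.51 ± 0.646 CPM (SD, n = 2; log2 change 1.75 ± 0.13 SE, edgeR adjusted p = 0.00466), and the repressor Cry1 at 15.6 against 7.48 (edgeR adjusted p = 0.0199). Dbp, an output transcription factor of the clock, was at 37.8 ± 2.37 against 174 ± 44.5 CPM (SD, n = 2; log2 change -2.21 ± 0.17 SE, edgeR adjusted p = 0.00613). Usp2 and Per3 fell with it, by 2.34 and 1.47 on the log2 scale (edgeR adjusted p = 0.00613 and 0.0391). The other called members, named after their values were seen, were Per2 and Bhlhe41, which fell by 1.26 and 2.08 (edgeR adjusted p = 0.0199 and 0.0357). Arntl lies on chromosome 7 from 113178471 to 113314126 and Dbp on chromosome 7 from 45705100 to 45710203 in mm10, and both are annotated as protein coding. The time of tissue collection is not given in the sources used here.

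Of 21 tested PPAR-alpha targets, a list that holds genes of fatty acid oxidation, 3 fell and none rose over all genes, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.31e-06, and adjusted p = 0.793 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, was at 340 against 607 CPM (edgeR adjusted p = 0.0143), Acot2, an acyl-CoA thioesterase, at 10.6 against 24.3 (edgeR adjusted p = 0.00782) and Vnn1 at 93.8 against 162 (edgeR adjusted p = 0.0307). Of 23 interferon response genes, 21 had log2 changes below 0, but 1 passed over all genes and 8 adjusted over the list alone (camera adjusted p = 3.70e-06, and adjusted p = 0.793 with an estimated correlation). That gene was Usp18, a feedback inhibitor of interferon signalling, at 16.9 against 27.7 CPM (edgeR adjusted p = 0.0187). Gbp7 and Zbp1 were at 18.8 and 12.9 against 26.0 and 18.3 (edgeR adjusted p = 0.0874 and 0.0887). Haemoglobin transcripts, a marker of blood in the section, were lower too: Hba-a2 fell by 1.04 and Hbb-bs by 0.78 on the log2 scale (edgeR adjusted p = 0.0142 and 0.0222), in a list of 5 tested erythroid genes (camera adjusted p = 1.31e-06, and adjusted p = 0.793 with an estimated correlation). The haemoglobin genes have near-identical copies, so their probes can capture more than 1 of them.

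Markers of Kupffer cells (resident liver macrophages), of recruited and lipid-associated macrophages and of fibrosis passed the list test downwards, but no single member passed over all genes or over the list alone. For Kupffer markers the camera adjusted p was 0.0143, and adjusted p = 0.915 with an estimated correlation. All 14 members had log2 changes below 0. Slc40a1, the iron exporter, was at 146 against 208 CPM (edgeR adjusted p = 0.133). In Timd4, Adgre1 and Marco, caloric restriction replicate 19 stood above the other 3 sections: Marco was at 123 CPM there, at 6.25 in caloric restriction replicate 18 and at 29.4 and 9.15 in the GDF15 sections. Clec4f, a Kupffer cell lectin, was at 343 in caloric restriction replicate 19 and 149 in replicate 18, against 193 and 202 (edgeR adjusted p = 0.618). The recruited macrophage list (camera adjusted p = 0.00174) and the fibrosis list (camera adjusted p = 0.00118) both had adjusted p = 0.793 with an estimated correlation. Mmp12, a macrophage elastase in the recruited list, was at 41.3 in caloric restriction replicate 19 and between 11.9 and 12.1 in the other 3 sections. Gpnmb and Trem2, markers of lipid-associated macrophages, had log2 changes of 0.17 and 0.04 (edgeR adjusted p = 0.836 and 0.900). The collagen gene Col1a1 was at 24.5 ± 8.0 against 41.0 ± 19.5 CPM (SD, n = 2; edgeR adjusted p = 0.285). Without caloric restriction replicate 19 the Kupffer list turned to higher after GDF15 (camera adjusted p = 0.000621), and the calls of the recruited macrophage and fibrosis lists were lost (camera adjusted p = 0.385 and 0.441). With a filter of 10 CPM all 3 calls were lost, at camera adjusted p = 0.418 for the Kupffer list, 0.200 for the recruited macrophage list and 0.198 for the fibrosis list.

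The remaining 18 lists did not pass the list test, and 8 of their 251 tested members passed over all genes. These were Cyp7a1, the rate-limiting enzyme of bile acid synthesis (log2 change -1.09, edgeR adjusted p = 0.0231), the bile salt exporter Abcb11 (0.67), Bcl6, Cish (-1.28), Fmo2 (-0.81), Cyp17a1 (0.64), Sox9 (0.70) and Cidec. No member of the lists of inflammatory cytokines and chemokines (22 genes), acute phase proteins (22 genes) or antigen presentation by MHC class II (8 genes) passed, over all genes or over the list alone. The chemokine Ccl2 was at 2.32 ± 0.73 against 2.99 ± 0.81 CPM (SD, n = 2; edgeR adjusted p = 0.50), and Saa1 was not analysed here. Transcripts of Gdf15 itself were at 184 ± 11.7 and 146 ± 15.3 (SD, n = 2; edgeR adjusted p = 0.208). The zonal enzymes Cyp2e1 and Cyp2f2 had log2 changes of -0.40 and 0.28 (edgeR adjusted p = 0.304 and 0.261). In 4 of the 29 lists the median log2 change and the direction of the list test differed in sign, and these were the growth hormone, male-biased, B cell and mesothelial lists.

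**Figure D1:**
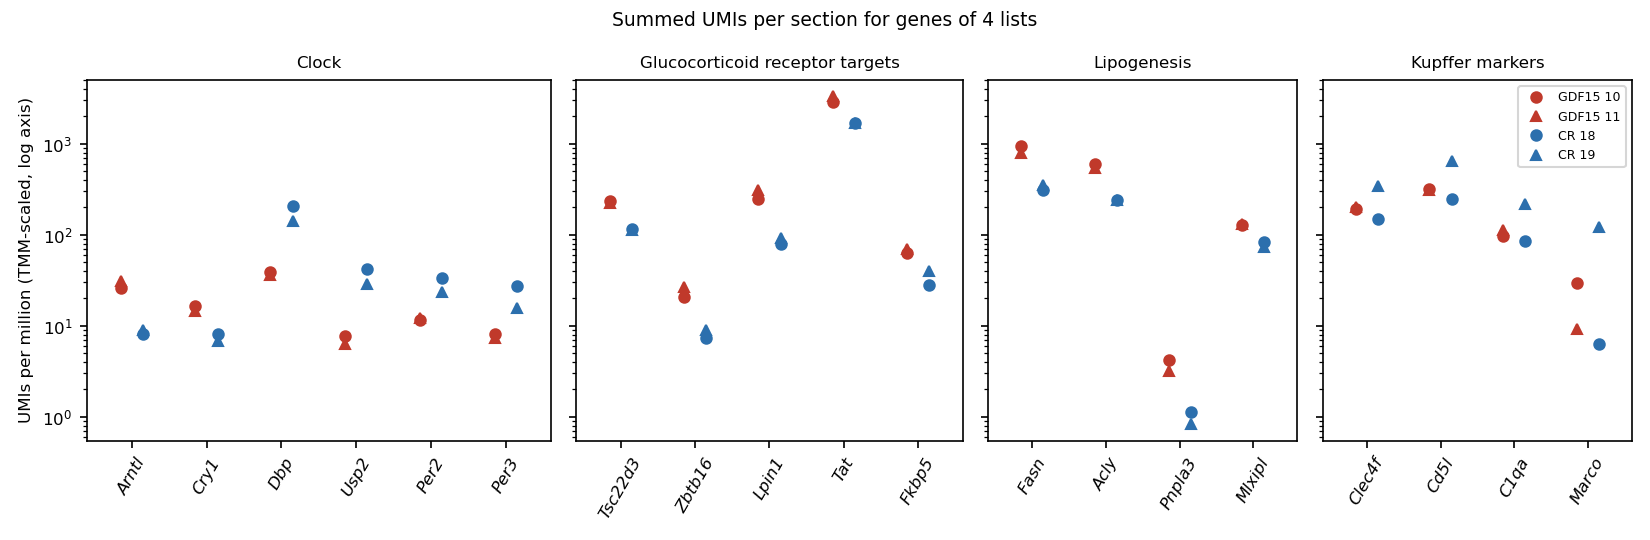
CPM (log axis) of named genes in each of the 4 sections, grouped by list; red symbols are the GDF15 sections, blue symbols those from caloric restriction (CR), and each symbol is 1 section. Both GDF15 sections lie on the same side of both others for the clock, glucocorticoid receptor and lipogenic genes shown, whereas Marco runs from 6.25 to 123 within caloric restriction.

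The spread of macrophage transcripts over the tissue was compared as the share of spots with at least 1 UMI of Gpnmb, Trem2, Itgax, Mmp12 or Cd9, after thinning every spot to 2000 UMIs. The share was 17.8% ± 2.79 after GDF15 and 18.3% ± 2.58 under caloric restriction (SD, n = 2), a difference of -0.50 percentage points (exact two-sided permutation p = 0.667). Since 2 sections against 2 allow no p below 0.333, this test cannot show whether the groups differ. The difference turned to 1.21 with Gpnmb and Trem2 only, to 1.48 without GDF15 replicate 10 and to 1.33 without caloric restriction replicate 19. Spots left out for having fewer UMIs numbered 6, 6, 3 and 5. Without thinning, the shares were 51.7% and 66.4%. For the Kupffer genes Clec4f, Vsig4, Cd5l, Timd4 and Marco, the thinned share was 64.0% (95% Wilson interval 62.7 to 65.4) and 65.2% (63.8 to 66.5) in the GDF15 sections. It was 52.4% (51.0 to 53.8) in caloric restriction replicate 18 and 87.9% (87.0 to 88.8) in replicate 19. These intervals cover counting error only. T and NK cell markers were seen in 5.39% and 4.39% of thinned spots (exact permutation p = 0.333), and cholangiocyte markers in 9.10% and 7.69% (exact permutation p = 0.333). In both, each GDF15 section lay above each section from caloric restriction once thinned. Without thinning, the means were 20.1% and 25.5% for T and NK markers, 30.6% and 35.2% for cholangiocyte markers, and 95.2% and 99.1% for the Kupffer genes.

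**Figure D2:**
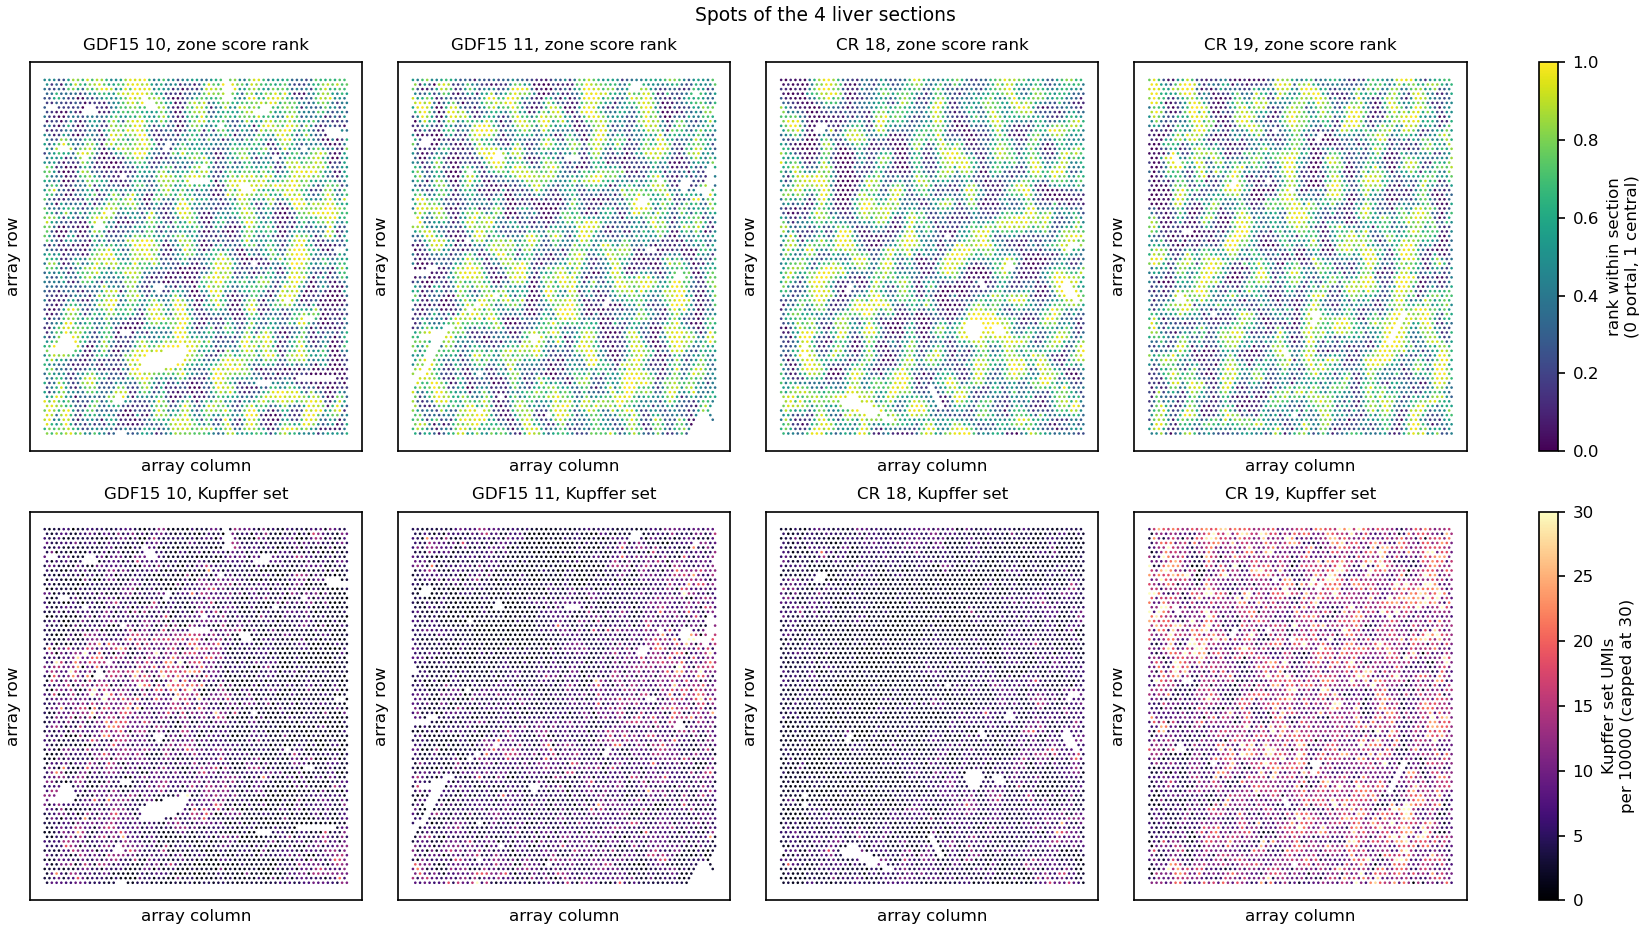
Spots of the 4 sections at their array positions; the upper row shows the rank of the zone score within each section (0 portal, 1 central) and the lower row the UMIs of the 5 Kupffer genes scaled to 10000 UMIs per spot, capped at 30. Central and portal spots alternate across every section, and caloric restriction replicate 19 shows more Kupffer signal than the other sections, with 1272 UMIs of the set per 1000000.

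Liver lobules were resolved by ranking spots on central against portal landmark genes, and the outer ranks at each end (the central and portal zones) were compared. The score was shared between neighbouring spots, with correlations across pairs of adjacent spots of 0.660, 0.647, 0.718 and 0.629 in the 4 sections; spots are not independent. Landmark genes left aside, 1968 genes were higher centrally and 1911 portally of 13481 tested (edgeR, section as a block, adjusted p under 0.05). Central genes with the largest differences included the carboxylate transporter Slc13a3 (37.0 against 3.64 CPM, 10.8-fold, edgeR adjusted p = 1.56e-11), Hao2 (8.29-fold) and the lipoprotein receptor Vldlr (7.70-fold). The transcription factors Sp5 and Tbx3, both targets of Wnt signalling, were 9.27-fold and 6.5-fold higher. Susd4, Cfd, Cidea and Cib2 were 6.31-fold to 7.0-fold higher, and Mup11, a major urinary protein gene whose close relatives can share probes, 6.21-fold. At the portal end, Scara3, Mgp, Tspan8 and Mmd2 were 7.83-fold to 9.03-fold higher, and Spp1, Epcam and Cdh1, all expressed by bile duct epithelium, 7.08-fold, 7.40-fold and 6.89-fold. Clec2h and C7 were also portal, at 6.63-fold and 5.75-fold. For Clec2h this value mainly reflects caloric restriction, with log2 ratios of central over portal of -2.85 and -2.04. In the GDF15 sections, where its counts were low, they were -0.75 and -1.57. Each of these genes differed the same way in 4 of 4 sections, which was a condition for being named. DESeq2 called 2079 genes.

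Several lists were zonal by camera with a preset correlation. Each list named next lost its call when the correlation between genes was estimated. Since no list at all passed then, even where every member was called alone, that test cannot tell the lists apart. All 10 tested cholangiocyte markers were portal, with a median log2 ratio of -2.16 (camera adjusted p = 1.25e-20, and adjusted p = 0.202 with an estimated correlation). Of 22 acute phase genes 18 were portal (camera adjusted p = 9.75e-13, and adjusted p = 0.226 with an estimated correlation), as were 12 of 17 recruited macrophage markers (2.04e-06, with adjusted p = 0.226 with an estimated correlation). The portal members of the latter list include Spp1, which bile duct epithelium expresses too, so this count does not place recruited macrophages. Of 20 glucocorticoid receptor targets, 11 were portal and 1 central (camera adjusted p = 0.00197, and adjusted p = 0.226 with an estimated correlation). Central lists included PPAR-alpha targets, with 17 of 21 members central (camera adjusted p = 2.87e-18, and adjusted p = 0.202 with an estimated correlation). Bile acid genes (9 of 14, camera adjusted p = 9.35e-14, and adjusted p = 0.119 with an estimated correlation) and endothelial markers (11 of 14, camera adjusted p = 2.09e-11, and adjusted p = 0.226 with an estimated correlation) were central as well. In all, 15 of 28 lists passed the preset test and 0 the estimated one. Central spots held fewer UMIs than portal spots in every section, for example medians of 16941 and 22330 in caloric restriction replicate 18.

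The central over portal ratio differed between the groups in 1 gene of 14898. Rgs16, a regulator of G protein signalling, had log2 ratios of -0.14 and -0.04 in the GDF15 sections and 0.51 and 0.81 under caloric restriction (interaction -0.74 ± 0.09 SE, edgeR adjusted p = 0.0146). It was thus central under caloric restriction and near even after GDF15. Among genes with at least 10 CPM and no overlap between groups, those with the next smallest p did not pass the threshold. Upp2, G6pc, the gluconeogenic phosphatase, Angptl8 and Fasn each had an edgeR adjusted p of 0.0571, with mean log2 ratios of 0.06, -0.18, -0.17 and -0.15 after GDF15 against -0.69, 0.35, 0.47 and 0.51 under caloric restriction. Aqp8 and Acss2 followed (edgeR adjusted p = 0.0801 and 0.0972), then Serpina1e, Ugdh and Wwtr1 (0.136 to 0.142). Serpina1e belongs to a cluster of near-identical copies and is uncertain. At an unadjusted p under 0.05 in edgeR there were 828 of the 14898 genes, little above the share this threshold passes where nothing differs. DESeq2 called 3 genes, and a filter of 10 CPM left 0 in edgeR (493 at an unadjusted p under 0.05). Without 1 section the count was 9 (GDF15 replicate 10), 4 (GDF15 replicate 11), 223 (caloric restriction replicate 18) and 210 (caloric restriction replicate 19).

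**Figure D3:**
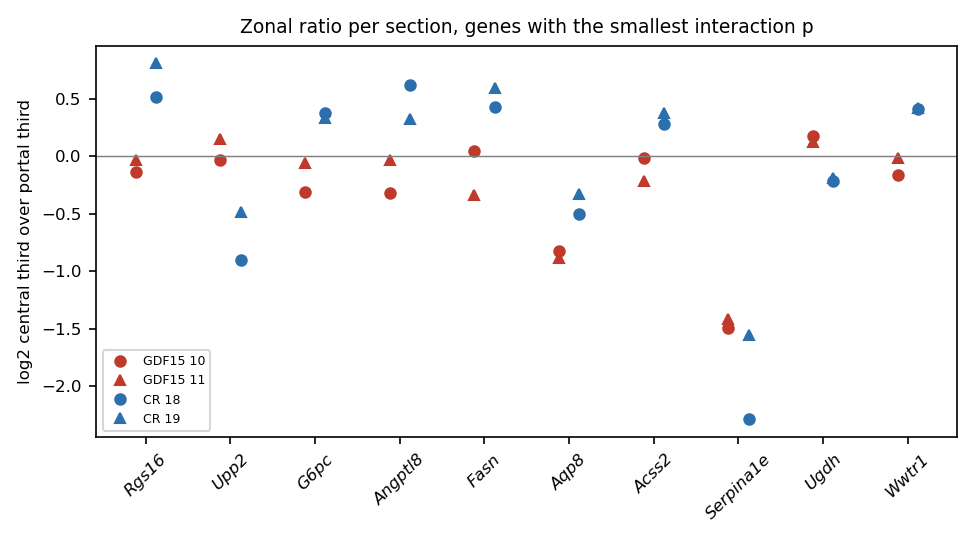
Log2 ratio of central over portal zone in each section for the 10 genes with the smallest interaction p among those with at least 10 CPM whose groups do not overlap; red symbols are GDF15 sections, blue symbols caloric restriction (CR), and the grey line marks equal levels. Rgs16, G6pc, Angptl8, Acss2 and Wwtr1 lie above the line in both sections from caloric restriction and below it in both GDF15 sections, Ugdh lies the other way, and of the 10 genes only Rgs16 passed the threshold.

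The groups were also compared within each zone. In the central zone 25 genes were higher and 40 lower after GDF15, and 64 of these 65 were also called over whole sections. In the portal zone 56 were higher and 55 lower, of which 103 of 111 were called over whole sections. Which direction held more genes was not stable: centrally DESeq2 called 113 higher and 87 lower, edgeR without GDF15 replicate 10 called 21 and 19, and portally edgeR without caloric restriction replicate 19 called 42 and 63. The zones shared 46 calls, and all 130 genes called in either zone had the same direction in both. The zones are parts of the same 4 sections, so overlap with the calls over whole sections is largely built in. Centrally, Bcl6 (log2 change 1.90), Lpin1 (1.73), Arntl (1.64), Zbtb16 (1.61) and Abtb2 (1.30) rose most, and Themis (-2.64), Usp2 (-2.15), Dbp (-2.13), Wee1 (-2.07) and Cntnap1 (-1.92) fell most, with edgeR adjusted p from 0.00362 to 0.0413. Portally, Atp2b2 (1.97), Arntl (1.88), Bcl6 (1.82), Fasn (1.72) and Lpin1 (1.69) rose most, and Clec2h (-3.52), Usp2 (-2.41), Dbp (-2.30), Pnldc1 (-1.63) and Osbpl3 (-1.39) fell most, with edgeR adjusted p from 0.00992 to 0.0451. The portal count was 0 without GDF15 replicate 10, without GDF15 replicate 11 and without caloric restriction replicate 18, with 1362, 1330 and 2432 genes at an unadjusted p under 0.05 in edgeR. The central count was 40, 6, 496 and 1091 without GDF15 replicates 10 and 11 and caloric restriction replicates 18 and 19.

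The authors' deposited table of spatial autocorrelation gives Moran's I per gene and section, a score that is high where neighbouring spots have similar levels. In the authors' deposited table, Cyp2e1, a central enzyme, stood at 0.547, 0.507, 0.557 and 0.505 in GDF15 replicates 10 and 11 and caloric restriction replicates 18 and 19. Rgs16 stood at 0.023 and 0.034 against 0.170 and 0.160 in the authors' deposited table, and Gpnmb at 0.077 and 0.240 against 0.246 and 0.082. Of 96 named genes with values in the authors' deposited table, 29 (30.2%) were higher in both sections from caloric restriction than in both others and 5 (5.21%) the other way; over all 19231 genes with values in the authors' deposited table these shares were 17.0% and 14.0%, and chance gives 16.7% per direction where sections are alike. Many of the 96 were named because they differed between the groups or zones of these sections, so their shares are not independent evidence. No test between the groups was made on the authors' deposited table, and whether the score varies with depth was not tested.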

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

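Every test below except that of a patch in 1 part of a section was chosen after the result it bears on, or values close to it, had been seen. Rgs16 drew attention because its central over portal ratio differed between the groups (interaction -0.74 on the log2 scale, edgeR adjusted p = 0.0146). The same test applied to lists, camera with a preset correlation, found a group difference in zonal ratio for 10 lists, none of which passed with an estimated correlation. Lists tilted less centrally after GDF15 were lipogenesis (median interaction -0.17 on the log2 scale), gluconeogenesis and amino acid breakdown (-0.085), cholesterol synthesis (-0.083) and PPAR-alpha targets (-0.020). Lists tilted more centrally were inflammatory cytokines and chemokines (0.24), interferon response (0.15), acute phase (0.078), NRF2 and oxidative stress (0.084), Kupffer cell markers (0.29) and recruited and lipid-associated macrophage markers (0.20).

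Zonal ratios differed between the groups in Rgs16 and, by the preset list test alone, in lipogenic genes as a list. A stronger zonal contrast overall in the sections from caloric restriction would change the size of ratios and keep their sign; 2 of the 18 members of the lipogenesis list had ratios of opposite sign in the groups in all 4 sections, too few to exclude it. Over the 3879 genes that differed between the zones, the median log2 ratio in the direction called was 0.31 and 0.28 in the GDF15 sections and 0.35 and 0.27 in those from caloric restriction, which overlap. Splits of the 4 sections are too few for a share under 0.05: the real split gave 1 gene and the highest of the others 2, so all 3 gave at least as many. The treatment stays open as an explanation, and so does any unrecorded difference between the sections, such as feeding before collection.

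Clock genes changed in both directions, with 2 higher and 5 lower after GDF15 of 17. All 7 called clock genes were still called with the same direction after thinning every section to the shallowest total. Thinning the sums keeps the expected proportion of each gene, so this bears on counting precision only. Whether a difference in depth came with a shift in proportions was not tested, so depth stays open. A different cell make-up stays open as part of the cause, since 9 of the 17 members of the clock list changed by more than the largest median of any cell type list in their direction, by more than 2 SE, and the others did not. A different time of day or of feeding at collection may account for the pattern: 16 of 17 genes assigned to a phase from general knowledge had the sign it predicts, 7 of them past the threshold in edgeR. The phases were assigned after the directions had been seen, and 2 genes were added once 15 of 15 had gone as predicted, so this count is weak evidence; the time is not given in the sources used here, and an effect of treatment on the clock cannot be told apart from it.

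Kupffer cell markers differed between the sections from caloric restriction. Depth is argued against, since at 2000 UMIs per spot the 95% intervals of the share of spots lay 33.2 percentage points apart. A lower share of hepatocytes would raise other cell types alike. However, the medians of 4 of 4 other marker lists lay below the lower quartile of the Kupffer list. These were the lists with at least 4 members at a mean of 5 CPM, hepatocyte markers left aside. As log2 of replicate 19 over 18, the medians were 0.54 (recruited macrophage), 0.37 (endothelial), 0.10 (cholangiocyte) and -0.0042 (stellate), against 1.35 for Kupffer markers. A patch in 1 part of the section is argued against, since the lowest ratio of replicate 19 over 18 among 4 equal areas of the section was 2.34, although the areas of GDF15 replicate 11 ranged from 404 to 711 UMIs of the Kupffer set per 1000000, so a region wider than the section stays open. Both sections belong to 1 group, and no biological explanation was tested.

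In edgeR, 204 genes differed over whole sections in the real split of the 4 sections and at most 0 in the other splits. Those had 286 and 422 genes at an unadjusted p under 0.05. There are too few splits (3) for a share under 0.05, and 1 split, the real one, gave as many. The other splits mix the groups on both sides, so a group difference widens the spread within sides and lowers their counts. Their 0 calls therefore do not measure chance. For the central and portal zones, swapping the zones in some sections gave at most 0 genes in edgeR against 3879. Up to 481 genes had an unadjusted p under 0.05 in edgeR after a swap. The 8 ways of swapping are too few for a share under 0.05, and 1 gave as many. Every section was ranked on the same landmark genes, so the loss of calls after a swap was built in. It cannot bear on chance.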

How the results depend on the processing

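No paired analysis was possible because the sample numbers of the groups do not overlap. Leaving genes of the non-hepatocyte lists out (239 genes called) and clock genes out of the other lists (11 lists) were chosen after the data were seen. The latter removed only Per1, from the glucocorticoid receptor targets, and left every other list as it was. Its unchanged count is therefore no check on those lists. Where no cause is given, the cause was not tested. For genes over whole sections (204), DESeq2 called 754, of which 203 were shared with edgeR, and equal weighting of spots 128, while the other settings with 4 sections gave 143 to 239. Without 1 section the count ran from 27 to 596; the lone section left in a group is then assumed to vary like the other group. Of the 33 named genes past the threshold, none changed sign in any alternative. Those named by size of change had been chosen for no overlap between groups. For them, a kept sign after leaving out 1 section was therefore largely built in. Many of the 33 lost their call without GDF15 replicate 10, and many without GDF15 replicate 11. For lists (11), camera with an estimated correlation and fry each gave 0, and without 1 section 11 to 16. A filter of 10 CPM left 8, of which 7 were among the 11, and ended the Kupffer, recruited macrophage and fibrosis calls (camera adjusted p = 0.418, 0.200 and 0.198). The list it added was integrated stress response and ER stress, upwards (camera adjusted p = 0.00623, against 0.0960 without that filter). The erythroid list had too few genes left to be tested. For zones (3879), DESeq2 gave 2079, and without 1 section 2633 to 3591. For the interaction (1), the outer 10% of ranks gave 6, Cyp2e1 and Cyp2f2 as landmarks 9, RLE factors 6, a filter of 10 CPM 0, DESeq2 3, and without 1 section 4 to 223. In the central zone (65), dividing at the median rank gave 132 and DESeq2 200, and without 1 section 6 to 1091. In the portal zone (111), it gave 203 and DESeq2 319, and without 1 section 0 to 105. The difference in share of spots with macrophage transcripts (-0.50 percentage points) turned to 1.21 with Gpnmb and Trem2 only, and ran from -2.47 to 1.48 without 1 section. Among named genes with values in at least 500 spots, 18 were higher in Moran's I in both sections from caloric restriction against 29 over all, since fewer genes were left (55 of 96). Genes that turned direction without 1 section had not passed in edgeR: their log2 changes ran from -1.50 to 0.33 for Adgre1, -0.80 to 0.40 for Clec4f, -0.39 to 0.91 for Gpnmb, -2.82 to 1.59 for Marco, -0.059 to 0.092 for Nr3c1, -0.47 to 0.068 for Per1, -2.17 to 0.59 for Timd4 and -0.16 to 0.20 for Trem2. The Kupffer list turned to higher without caloric restriction replicate 19, and with 1 section left out its camera adjusted p ran from 5.12e-32 to 0.0212. Thinning every section to the shallowest total, 35192332 UMIs, gave 235 genes over whole sections.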

Other observations

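The following genes were chosen after their values were seen, as a part of the 15 largest differences in each direction between the sections of a group, among genes with a mean of at least 10 CPM there; others of the 15 are not named, and no test was made between single sections. In GDF15 replicate 11, Egr1 and Fos, transcription factors induced within minutes of a stimulus, were at 308 and 60.8 CPM against 52.5 and 12.7 in replicate 10. The metallothioneins Mt1 and Mt2 were 5.96-fold and 7.99-fold higher, the neutrophil chemokine Cxcl1 6.0-fold (203 against 33.3), Foxq1 5.11-fold, Gadd45g 4.89-fold, Btg2 4.61-fold, Nr4a1 4.01-fold and Socs3, a feedback inhibitor of cytokine signalling, 3.65-fold. Igfbp1, an insulin-repressed secreted protein, was at 619 against 245. Lower in replicate 11 were Marco (9.15 against 29.4), the hormone gene Fgf21 (6.09 against 19.1), Acot3 (10.3 against 29.4), Angptl8 (58.3 against 130), Tsku (28.3 against 62.4), the chaperone gene Dnajb9 (47.8 against 97.1), Creld2 (33.2 against 61.9) and Inhbe (18.8 against 34.6).

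Within caloric restriction, the hepatocyte marker list had a median of -0.18 as log2 of replicate 19 over replicate 18. The organic anion transporter Slco1a1, a male-biased gene, was at 0.59 CPM in replicate 19 against 28.9 in replicate 18, Cyp2c54 at 13.6 against 128 and Sult2a8 at 157 against 400. The urinary protein genes Mup10 and Mup17 were 2.27-fold and 2.11-fold lower, and Serpina1e 5.92-fold lower. Members of the Cyp2c, Mup and Serpina1 families have near-identical copies, so these values are uncertain. Ly6d was at 122 against 21.5 and the cell cycle inhibitor Cdkn1a at 30.0 against 10.7, while both GDF15 sections had 69.1 and 79.8 for Cdkn1a. The receptor gene Egfr was at 34.0 against 74.7, and Gpnmb, expressed by lipid-associated macrophages, at 19.4 against 44.7.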
